A study of Sus scrofa with 88 samples.

How the data were processed

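Gene expression was measured in IPEC-J2, an enterocyte cell line from piglet jejunum, on Agilent 1-colour arrays for the pig with Cy3-labelled RNA. The 88 arrays carry 44 RNA pools. Per the labels' protocols, RNA was isolated with TRIzol, treated with DNase and labelled with a Low Input Quick Amp kit, the RNA of duplicate wells was pooled, and each pool was hybridised to 2 arrays. The pool was therefore taken as the replicate, and the arrays of a pool were averaged before any fit. No label says that pools came from separate cultures, so the spread between these pools may be partly technical. Of the 42 groups by additive, concentration, time and bacteria, 40 have 1 pool, so the fits hold few replicate pools. Their p-values rest mostly on how the effects differ between conditions.

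The deposited scanner files hold spot intensity on a linear scale, extracted with Feature Extraction 11.5.1.1 under the protocol GE1_1105_Oct12, per the file headers. Each array had 45122 spots, of which 1319 were control spots that were left out, and the remaining spots stood for 43603 probes. The main measure was the log2 of the processed signal, which Feature Extraction has already corrected for background, minus the log2 of the 75th percentile of that signal on the same array. That percentile was between 60.1 and 490 per array. The authors' value table in the series matrix also holds intensity. Its columns matched the background-subtracted signal of the same arrays to within 0.00478, their medians ran from 6.47 to 57.24, and it was on a linear scale without centring or scaling between arrays. It was used as an alternative after the same scaling, with low values set to a floor of 0.0353 of the 75th percentile.

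Between 16709 and 29784 probes per array were well above background, with a median of 22155, and 0 spots were saturated. At most 60 spots of an array carried an outlier flag. In all, 577 probe values with such a flag were left out, except for 26 pool values where both arrays carried it, which were kept. A probe was tested when it was well above background on both arrays of at least 2 pools, which left 27217 probes. Gene names came from the scanner files' identifiers, matched without versions to a RefSeq gene table. Of the probes, 6686 matched 1 RefSeq gene and 6585 had a symbol other than a LOC name, from 2962 genes; 8220 probes carried only an Ensembl transcript identifier and stayed unnamed here. After the filter 2397 named genes were left, each represented by the probe with the highest mean signal, and disagreement of a gene's other probes is stated where the gene is named. Columns of per-sample values that were not used numbered 0.

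Tests used limma 3.58.1 with a mean-variance trend in R 4.3.3 (data.table at version 1.17.8, statmod 1.5.0), with Benjamini-Hochberg adjustment over the 27217 probes and a threshold of 0.05 on the adjusted p. A fit over all 44 pools held the 4 conditions (2 h or 6 h, without or with bacteria) and the additive with its concentration, and left 28 residual degrees of freedom. It gave the effects of the bacteria, of time and of each additive at its highest concentration, an effect taken as common to the 4 conditions. The interaction of additive with bacteria or with time was added to this fit, with 21 degrees of freedom. Lower concentrations, incubated only for 6 h, were compared in a fit of the 28 pools at 6 h with 14 degrees of freedom. In the text ± is the standard error of the fit unless SD is given, and n is the number of pools.

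The samples, comparisons, tests, alternatives and the rule for naming genes were fixed before the data were examined. Of the genes past the threshold with a symbol that is no accession, clone or LOC name, the text names the 10 largest rises and 10 largest falls for the effect of bacteria at each time, for 6 h against 2 h and for ZnO, 5 and 5 for the other additives, 3 and 3 for other comparisons, and the 5 smallest p for F tests. Of each gene list described, it names the up to 4 members with the smallest adjusted p. A few genes that meet these rules are left out of the text. Genes with another probe past the threshold in the opposite direction were passed over, 5 for bacteria at 6 h and 5 for 6 h against 2 h. A gene whose probe was not well above background on any array of 1 group is given as a lower bound, from the mean of the brighter group over that of the higher, per array, of the dim probe's own signal and the lowest signal well above background.

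Gene lists for inflammation, stress, metabolism, epithelial function, the cell cycle and other cell types were also fixed beforehand. Of the 24 lists, 23 were tested with limma's camera at a preset correlation between genes of 0.01 over the 2397 named genes, and 1 had 2 measured members and was not tested. The adjusted p of a list is over the 23 lists. Each list was also tested with the correlation estimated from the data and with fry, which asks whether a list's genes move one way on balance without setting them against other genes.

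The steps were tested on simulated data with the real spread, seed 1, on the 27217 probes, with 100 probes changed by 1 and 100 by 2 on the log2 scale. The simulated noise was independent between probes and pools, without slide, scan day or interaction effects. The false calls below therefore hold for such data and may be more in the real data. For bacteria at 6 h, 78% and 99% were recovered, with 8 false among 185 calls. At 2 h the shares were 62% and 96%, with 3 false of 161. For 6 h against 2 h they were 62% and 98% (8 false of 168), for ZnO 48% and 87% (10 of 145), for 9631 46% and 86% (5 of 137), and for PSA1 against PSA3 56% and 84% (7 of 147). Comparisons with fewer pools recovered less: 25% and 53% for the lower concentration of PSA2 (7 of 85), 5% and 53% for the highest against the lower concentration of ZnO (1 of 59), and 11% and 55% for the change of the response to bacteria by PSA2 (5 of 71). In a simulation of the ZnO comparison, 1 raised list was called with adjusted p = 3.04e-38, and 0 other lists were called. Genes were uncorrelated there, so this does not test lists of correlated genes.

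Alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, the authors' value table, the arrays as observations with the pool as a random block, the same with the hybridisation number or the slide as a block, only the pools compared, only medium pools, and each pool (or additive) left out in turn. The scanner files used here hold no mean signal, so normexp used the median signal. Scan day as a block, fits within each of 3 scan days, the letter of the pool code, the least agreeing pool, probes far apart on the arrays of a pool, and interactions fitted at 6 h alone were added after seeing the data. The arrays lie on 12 slides. Precision is limited by the number of pools: 40 of the 42 groups have 1 pool. RNA quality measures were not analysed here.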

Results

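Transcript levels were measured in IPEC-J2 monolayers, a model of the piglet intestinal epithelium, incubated with feed additives in the absence and presence of enterotoxigenic Escherichia coli (ETEC), a cause of diarrhoea in piglets. The study asked how soluble polysaccharide preparations of algae change the immune and metabolic state of these cells. The additives were 6 preparations known here only by their codes, 9631, PSA1, PSA2, PSA3, PSY1 and PSY2, and zinc oxide (ZnO). Their highest concentrations were 0.052% (w/v) for PSA1 and PSA3 and 0.01% for the others. PSA1 and PSA3 were also used at 0.0052%, PSA2 and PSY2 at 0.001%, and ZnO at 0.0001%. Cells in medium alone were the control.

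The 88 arrays held 44 RNA pools, 22 without and 22 with ETEC, 16 after 2 h and 28 after 6 h. Each additive at its highest concentration had 4 pools, 1 per time with and without ETEC, and each lower concentration had 2, both at 6 h. Medium had 6 pools, of which 4 were at 6 h. The median correlation between both arrays of a pool was 0.966 (44 pairs, 0.882 to 0.986), with the lowest value in the pool of PSA3 0.0052% without ETEC. Arrays of different pools had a median of 0.950 (0.856 to 0.993). All 32 arrays of the 2 h pools were scanned on the third of 3 scan days, with 11 of the 6 h arrays, and the other 6 h arrays on the first 2 days (24 and 21 arrays). Medium pools at 6 h were scanned on days 1 and 2, and the 6 h pools of 9631 and PSY1 on day 3. The other additives at their highest concentrations had their 6 h pools on days 1 and 2. For these, values within day 3 come from 2 h and those within days 1 and 2 from 6 h. PSA1 0.0052% was scanned on day 3 without ETEC and on day 2 with it. On day 3 only 9631 and PSY1 had both pools of a pair at 6 h.

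At 2 h, ETEC changed none of the 2397 named genes past the threshold. The 2 probes that rose carry no gene name, A_72_P443667 by 2.40 ± 0.24 (log2, adjusted p = 3.23e-07) and A_72_P370198 by 1.58 ± 0.25 (adjusted p = 0.00542), each in 8 of 8 pairs of pools. They were above background on 10 and 5 arrays with ETEC at 2 h and on 0 without, which bounds the rises to at least 2.58-fold and 1.66-fold. At 6 h they rose by at least 65.4-fold and 29.5-fold. No member of a gene list passed at 2 h. As groups, camera set the integrated stress and unfolded protein response list higher (13 genes, mean 0.20, adjusted p = 0.000526), mucins and epithelial defence lower (17 genes, mean -0.19, adjusted p = 0.000526) and p53 targets higher (11 genes, mean 0.15, adjusted p = 0.0119). With an estimated correlation the adjusted p of these lists was 0.232, 0.374 and 0.468.

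In limma's test 2 of 27217 probes passed, and 185 had an unadjusted p under 0.05, where chance gives 1361. The p-values at 2 h thus ran larger than chance gives, so the missing calls do not show that ETEC had no effect. The fit holds no term for additive by time, so it does not match the pools of a pair within 2 h. A fit of the 2 h pools alone does match them by additive, with fewer degrees of freedom, and 1 probe passed there. The 95% intervals reached a median of 0.414 to each side, and for 91.7% of the named genes the interval lay within 1 log2 unit of 0. The count was 0 with normexp, 1 with the authors' value table, 4 with arrays as observations, 5 with slide and 4 with scan day as a block, and 1 within scan day 3. It was 1 without the medium pools, 1 without those of PSY2 and 1 without those of ZnO at its highest concentration.

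After 6 h, ETEC raised 255 named genes and lowered 273. The largest rise was that of DDIT4, an inhibitor of mTORC1 signalling induced by stress, by 4.81 ± 0.25 (adjusted p = 6.95e-16, higher in 14 of 14 pairs). STC2, a secreted glycoprotein, rose by 3.54 ± 0.24. Among genes of secreted immune mediators, IL1A rose by 3.50 ± 0.29, the neutrophil chemokine CXCL8 by 3.27 ± 0.25, the growth factor CSF2 by 3.22 ± 0.32 and the chemokine CCL20 by 3.17 ± 0.32. The vasoconstrictor peptide gene EDN1 rose by 3.06 ± 0.25, the cornified envelope gene IVL by 2.99 ± 0.36 and the stress cytokine GDF15 by 2.98 ± 0.18. CD69 was not well above background on any of 28 arrays without ETEC and was so on 25 of 28 with it, at least 7.63-fold higher. Each of these had the same direction in 14 of 14 pairs except CD69, with 13.

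KITLG, which encodes stem cell factor, fell by 2.03 ± 0.17, HPS6, a gene of lysosome-related organelle biogenesis, by 2.01 ± 0.10 and the metalloprotease gene ADAMTS1 by 1.99 ± 0.26, each in 14 of 14 pairs. Falls between 1.13 and 1.40 were measured for THAP2, SOX2, SPAM1, the splicing factor gene SRSF6, the thioredoxin reductase gene TXNRD1, the transcription factor gene KLF2 and the heat shock gene HSPA6, in 12 to 14 pairs. The adjusted p of these 20 genes was at most 0.000101. The only other KLF2 probe had the opposite sign, short of the threshold. EDN1 and SRSF6 belong to probes that lay far apart on the arrays of at least 1 pool, and within scan day 3 SRSF6 was at 0.36. The plot of ETEC-responsive genes at 6 h shows 6 of the genes in every pool.

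**Figure D1:**
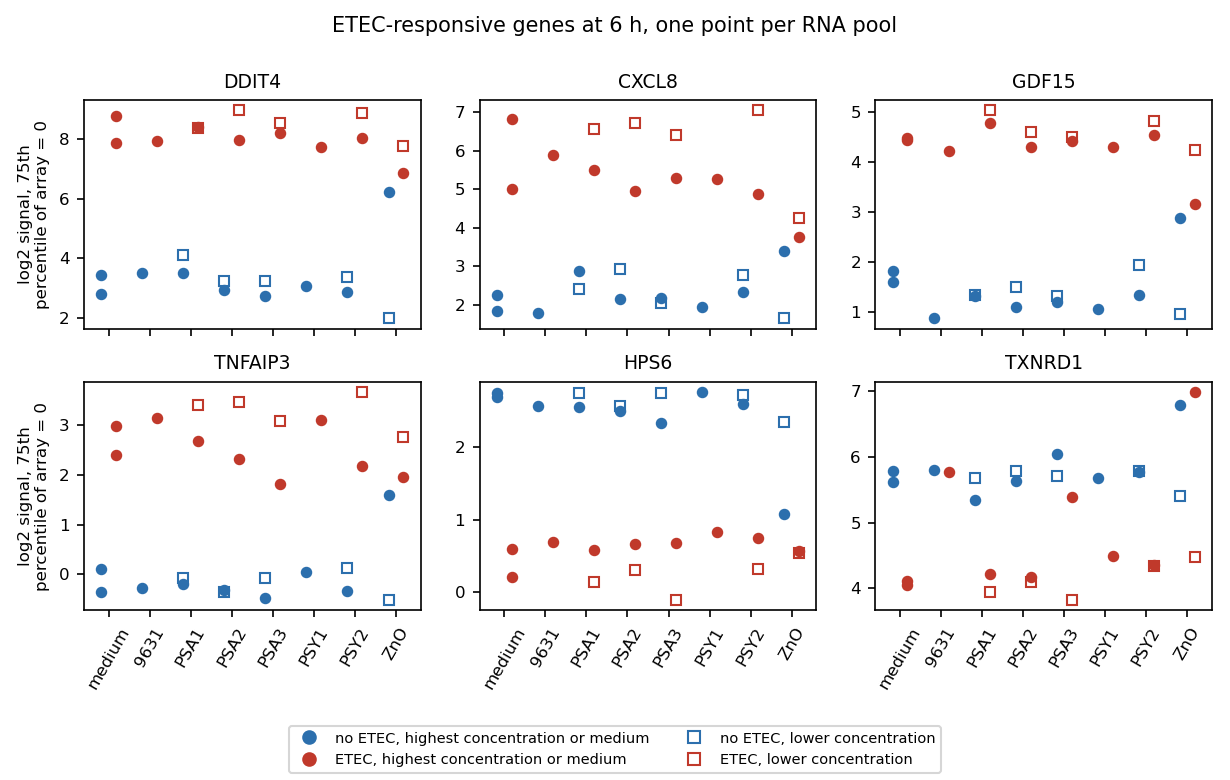
Levels of 6 genes in the 28 pools at 6 h, as log2 signal with the 75th percentile of each array at 0, by additive, without ETEC (blue) and with ETEC (red). Each point is 1 pool, filled for medium and the highest concentration and open for the lower one; DDIT4, CXCL8, GDF15 and TNFAIP3 lie higher and HPS6 and TXNRD1 lower with ETEC, and the pools with ZnO 0.01% differ least.

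Inflammatory cytokines and chemokines rose as a group: 10 of 15 measured genes passed upwards and 0 downwards (10 and 1 adjusted over the list alone), with a mean of 1.41 and CXCL2 up by 2.05 ± 0.19. Of 8 NF-kappaB regulators and targets 6 rose and 0 fell (6 adjusted over the list alone), among them TNFAIP3, which restrains this pathway, by 2.86 ± 0.18, PTGS2, the inducible cyclooxygenase, by 2.19 ± 0.17, the inhibitor NFKBIA by 2.04 ± 0.23 and the adhesion gene ICAM1 by 0.51 ± 0.08. In the integrated stress and unfolded protein response list 8 of 13 genes rose and 1 fell (8 and 1 adjusted over the list alone). DDIT3, a transcription factor of stressed cells, rose by 1.88 ± 0.18 and CTH, an enzyme of cysteine synthesis, by 1.27 ± 0.15. Among EGFR ligands and extracellular proteases 8 of 15 rose and 1 fell (8 and 1 adjusted over the list alone), with the ligand HBEGF up by 2.50 ± 0.20, tissue factor (F3) by 1.49 ± 0.14 and the plasminogen activator PLAU by 1.22 ± 0.13. Camera's adjusted p for these 4 lists was 6.91e-08, 2.13e-06, 2.13e-06 and 0.000257, and with an estimated correlation 0.0353, 0.0222, 0.0222 and 0.0222.

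Immediate early genes rose in 11 of 15 cases and fell in 2 (11 and 2 adjusted over the list alone), with BTG2 up by 2.27 ± 0.15, CTGF by 1.70 ± 0.12 and JUN by 1.41 ± 0.12 while KLF2 fell by 1.18 ± 0.11 (adjusted p = 5.99e-07; adjusted p = 0.0626 with an estimated correlation). Of 13 genes of hypoxia and glycolysis 6 rose and 0 fell (9 adjusted over the list alone), including hexokinase 2 (HK2) by 2.41 ± 0.17, adrenomedullin (ADM) by 2.10 ± 0.20, VEGFA by 1.11 ± 0.12 and P4HA1 by 1.13 ± 0.26, whose probe was also far apart in some pools. In the medium pairs P4HA1 was at 0.735 and -0.005. The list's adjusted p was 3.53e-06, and the adjusted p = 0.114 with an estimated correlation. Of 11 p53 targets 3 rose (3 adjusted over the list alone), GADD45A by 2.68 ± 0.23, BCL2L1 by 0.58 ± 0.13 and PMAIP1 by 0.94 ± 0.22, while FAS was at 0.22 ± 0.10 (adjusted p = 0.102) and at -0.10 in medium pools alone. The list's adjusted p was 0.0204, 0.274 with an estimated correlation.

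Genes of the oxidative stress response governed by NRF2 went the other way, with 4 of 12 lower and 0 higher (4 adjusted over the list alone): TXNRD1 fell by 1.18 ± 0.14, NQO1 by 0.44 ± 0.10, GCLM by 0.34 ± 0.10, and KEAP1, the repressor of NRF2, by 0.50 ± 0.08. The list's adjusted p was 0.0104, and adjusted p = 0.284 with an estimated correlation. Within scan day 3 its mean was 0.14 and its median 0.05, against a test direction of down (adjusted p = 0.936). That day held complete pairs at 6 h only for 9631 and PSY1, so scan day and these preparations cannot be told apart. Of 9 cell cycle genes 5 fell and 0 rose (6 adjusted over the list alone), among them the phosphatase gene CDC25C by 0.58 ± 0.07, the kinase genes AURKA by 0.43 ± 0.10 and AURKB by 0.40 ± 0.10, and CDC20 by 0.39 ± 0.11 (list adjusted p = 0.00151; adjusted p = 0.231 with an estimated correlation). With the letter M in the fit AURKA (adjusted p = 0.0631), AURKB (0.0668), CDC20 (0.119), NQO1 (0.0731) and GCLM (0.208) did not pass, nor did CDC20 without the medium pools (0.0696). Lists that camera did not call at 6 h had adjusted p from 0.108 to 0.915. Markers of leukocytes had 1 of 9 genes higher and 1 lower (adjusted p = 0.808) and those of fibroblasts and smooth muscle 2 of 10 higher (adjusted p = 0.117).

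In all, 6783 of 27217 probes passed in limma's test of ETEC at 6 h (14 pools with, 14 without), 2638 higher and 4145 lower, of which 519 and 677 by over 2-fold. With normexp 4309 passed, with the letter M of the pool code and its interaction in the fit 3648, and in medium pools alone (2 against 2) 806. In medium pools alone 24 of the 49 named genes lost the threshold and 1 changed sign. All 49 named genes kept their direction with the slide or the scan day as a block. Within days 1, 2 and 3 the counts were 2697, 369 and 1319, the shares of the 6783 probes with the same sign 99.8%, 98.8% and 94.7%, and the named genes with the same sign 49, 49 and 46 of 49 (SRSF6, NQO1 at 0.01 and GCLM at 0.04 reversed on day 3). DDIT4 rose by 4.75 with the slide and 4.83 with the scan day as a block, and by 4.99, 4.30 and 4.54 within the days. The mean of the inflammatory list was 1.43 and 1.45 with these blocks and 1.47, 1.09 and 1.51 within the days, that of the cell cycle list -0.25 and -0.30 and -0.36, -0.28 and -0.23, and that of the NRF2 list -0.20 and -0.29, then -0.45 and -0.20 on days 1 and 2. The other 6 lists stayed above 0 in each, with 1 lost call, that of p53 targets within day 3 (adjusted p = 0.0511).

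The response to ETEC was larger at 6 h than at 2 h for 82 named genes in the upward direction and for 59 downwards. DDIT4 gained 4.08 ± 0.42 (adjusted p = 9.58e-08), CCL20 3.20 ± 0.54, and CD69, near background without ETEC, also gained (adjusted p = 6.32e-06), while the effect on HPS6 dropped by 1.92 ± 0.17, on ADAMTS1 by 1.85 ± 0.43 and on KITLG by 1.77 ± 0.29. Of the inflammatory list 7 of 15 genes gained (9 adjusted over the list alone), of NF-kappaB regulators 4 of 8 (6), of the integrated stress list 4 of 13 (5), of EGFR ligands and proteases 6 of 15 with 1 lower (7 and 1) and of immediate early genes 9 of 15 with 1 lower (10 and 1). Their adjusted p was 5.44e-08, 5.47e-06, 2.93e-05, 0.000528 and 1.71e-07, and with an estimated correlation 0.0336 for the first 4 and 0.0486 for the last. The lists of hypoxia and glycolysis, NRF2, cell cycle, heat shock and secretory and stem cell markers were also called, with 3 of 13 higher, 2 of 12 lower, 1 of 9 lower, 1 of 14 lower and 1 of 5 higher and adjusted p = 0.112, 0.256, 0.216, 0.444 and 0.139 with an estimated correlation (5.30e-06, 0.00530, 0.00286, 0.0495 and 0.0323 without). In the test of the difference 2012 probes passed, 674 higher and 1338 lower. There were 1268 with normexp, 1146 with the letter M in the fit, 3294 with slide and 3102 with scan day as a block, and 897 within day 3, where 2011 of the 2012 probes had the same sign. With normexp ADAMTS1 (-0.37, adjusted p = 0.218) and KITLG (-0.23, adjusted p = 0.443) did not pass.

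Between 2 h and 6 h without ETEC, 60 named genes rose and 220 fell. The largest rises were those of ATP4A by 1.34 ± 0.32, TMCO1 by 1.32 ± 0.44, the lysosomal membrane gene LAMP1 by 1.13 ± 0.38 and RAB3A, at least 1.22-fold higher. Rises between 0.91 and 1.03 were measured for PTMA, PRRT1, the ribosomal protein gene RPL6, the nucleotide receptor gene P2RY6, the transcription factor gene HNF4A and the ribonuclease gene ANG. The largest falls were those of the prohormone convertase gene PCSK1 by 2.50 ± 0.48, PROX1 by 2.27 ± 0.51, CD72 by 2.12 ± 0.43 and MYH4 by 2.11 ± 0.43. Falls between 1.73 and 1.96 were measured for PNLIP, AMBP, HOPX, AQP1, OBP2B and SLC28A1. Of the cell cycle list 1 of 9 genes rose (6 adjusted over the list alone; adjusted p = 0.0118) and of heat shock proteins 2 of 14 (adjusted p = 0.026), both with adjusted p = 0.773 with an estimated correlation. In limma's test 3293 probes passed, 969 higher and 2324 lower.

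Scan day and time overlap in this comparison, since every array at 2 h was scanned on day 3. The count was 18 with the slide and 1804 with the scan day as a block, 1585 within day 3 (89.3% of the probes with the same sign), 1291 with normexp, 1472 without PSA1 and 1957 without PSA2 at their highest concentrations. None of the 20 genes kept an adjusted p under the threshold with either block, the lowest being 0.146 and 0.0840 for ANG. With normexp all of them but PTMA, PRRT1, RPL6, ANG and PCSK1 lost it. PROX1 was then at -0.72, CD72 at -0.52, MYH4 at -0.54, RAB3A at 0.11 and HNF4A at 0.07, while TMCO1 stayed at 1.29. PTMA, PRRT1, RPL6, P2RY6, PNLIP, AMBP and OBP2B changed sign with the slide as a block (-0.01, -0.22, -0.28, -0.37, 0.05, 0.07 and 0.73), and PTMA, RPL6 and P2RY6 with the scan day (-0.23, -0.31 and -0.02). Within day 3 RAB3A, PTMA, RPL6, HNF4A and ANG did (-0.15, -0.12, -0.06, -0.35 and -0.10). The 10 genes that fell were above background on 6 to 13 of 16 arrays at 2 h, and each has a probe far apart on the arrays of some pool. Of the 12 other RPL6 probes 6 had the opposite sign, as had the only other PTMA probe. When pools of 1 additive or of medium were left out, TMCO1, LAMP1, RAB3A and HNF4A lost the threshold 8, 9, 8 and 5 times in 13 fits, and AMBP (adjusted p = 0.0645) and SLC28A1 (0.0725) without PSA1 at its highest concentration.

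ZnO at 0.01% raised 131 named genes and lowered 28 against medium. HSPA6, an inducible HSP70 chaperone, rose by 7.43 ± 0.36 (172-fold, adjusted p = 1.17e-16) and heme oxygenase 1 (HMOX1) by 5.12 ± 0.28 (34.8-fold, adjusted p = 4.08e-15), each in 4 of 4 conditions. The signalling regulator RGS2 rose by 3.92 ± 0.30, AMPD1 by 3.30 ± 0.33, the chaperone genes HSPA1L by 3.26 ± 0.35, HSP70.2 by 3.17 ± 0.31 and DNAJB1 by 2.99 ± 0.18, the transcription factor genes FOS by 3.21 ± 0.34 and NR4A3 by 3.09 ± 0.26, and LAG3, above background on 1 of 12 medium arrays, by 3.01 ± 0.49. The gene of the cytokine IL6 fell by 1.34 ± 0.26 (adjusted p = 0.000315), BGLAP by 1.35 ± 0.19, KITLG by 1.22 ± 0.30, the cell cycle inhibitor CDKN1B by 1.02 ± 0.17 and HPS6 by 0.83 ± 0.18. DIRAS2 was at least 2.16-fold lower, and AMHR2, PDE4B, IFN-DELTA-6 and APOM fell by between 1.06 and 1.18. The fall was seen in 3 of 4 conditions for AMHR2 and HPS6 and in 4 for the others, and the other probe of PDE4B and of APOM had the opposite sign.

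Of the heat shock proteins and chaperones 9 of 14 rose and 0 fell (10 adjusted over the list alone), with a mean of 1.76. Immediate early genes rose in 11 of 15 cases and fell in 0 (13 and 1 adjusted over the list alone), with a mean of 1.45, among them KLF4 by 2.43 ± 0.20 and BTG2 by 2.16 ± 0.26. Both lists kept their call with an estimated correlation (adjusted p = 3.83e-17 and 2.04e-22; 0.000458 for each when estimated). Of 12 NRF2 genes 4 rose and 0 fell (4 adjusted over the list alone): HMOX1, TXNRD1 by 1.52 ± 0.23, the glutathione synthesis gene GCLM by 1.35 ± 0.17 and the quinone reductase gene NQO1 by 1.03 ± 0.18 (adjusted p = 0.000808; adjusted p = 0.229 with an estimated correlation). In the metallothionein and zinc transport list 2 of 9 genes rose (2 adjusted over the list alone), the zinc exporter SLC30A1 by 1.89 ± 0.14 and the metal-binding MT1A by 1.81 ± 0.19, while MT3 was at 0.41 ± 0.27 and SLC30A7 at 0.25 ± 0.16 (adjusted p = 0.00832; adjusted p = 0.0643 with an estimated correlation).

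Among secretory and stem cell markers 2 of 5 rose (2 adjusted over the list alone), CHGB, a granin of enteroendocrine cells, by 1.52 ± 0.30 and SOX9, a transcription factor of crypt cells, by 1.59 ± 0.35 in 3 of 4 conditions, with SPDEF at 0.66 ± 0.39 and CCK at 0.18 ± 0.24 (adjusted p = 0.0172; adjusted p = 0.126 with an estimated correlation). Of 9 cell cycle genes 1 fell (2 adjusted over the list alone), CDC20 by 0.69 ± 0.20, and AURKB was at -0.48 ± 0.17, TOP2A at -0.36 ± 0.18 and CCNB1 at -0.29 ± 0.15 (adjusted p = 0.00832; adjusted p = 0.345 with an estimated correlation). With the slide as a block neither list passed (adjusted p = 0.0970 and 0.0760), and within day 3 the cell cycle list had a mean of 0.06 and a median of 0.03 (adjusted p = 0.716). The ZnO 0.01% pools on day 3 were those at 2 h, so time and scan day cannot be told apart here. Ribosomal proteins were called lower with 0 of 17 genes past the threshold (adjusted p = 0.0406; adjusted p = 0.852 with an estimated correlation). The inflammatory list had 0 of 15 genes higher and 1 lower (adjusted p = 0.268), leukocyte markers 1 of 9 lower (adjusted p = 0.718).

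In limma's test of ZnO at 0.01% (4 pools against 6) 2776 probes passed, 1129 higher and 1647 lower, and 670 and 1191 of them by over 2-fold. Without ZnO at 2 h DIRAS2 did not pass (adjusted p = 0.0503), nor CDC20 without ZnO at 6 h (0.185). With normexp 1602 passed, without DIRAS2, KITLG, AMHR2, PDE4B, IFN-DELTA-6 and APOM (adjusted p from 0.267 to 0.930). These genes then lay between -0.21 and -0.34. With the compared pools alone 1816 passed, without DIRAS2, KITLG, AMHR2, HPS6, CDC20 and SOX9 (0.0857 to 0.173). All 37 named genes kept their direction with slide or scan day as a block, and 36, 34 and 36 of them within days 1, 2 and 3, where 3139, 1296 and 2179 probes passed. Days 1 and 2 held the 6 h pools of ZnO 0.01% and day 3 those at 2 h, so these days also differ in time. HSPA6 rose by 7.16 and 7.40 with these blocks and by 7.88, 7.64 and 7.03 within the days, HMOX1 by 5.08 and 5.12 and by 5.93, 5.28 and 4.54. List means with slide and scan day as blocks and within the days were 1.77, 1.76, 1.93, 2.04 and 1.55 for heat shock proteins, 1.57, 1.45, 1.12, 1.37 and 1.76 for immediate early genes, 0.83, 0.76, 0.65, 0.90 and 0.81 for NRF2 (with a median of -0.13 on day 1), 0.56, 0.49, 0.66, 0.40 and 0.47 for metallothioneins (adjusted p = 0.106 on day 2) and 0.74, 0.85, 0.91, 0.60 and 1.04 for secretory markers (adjusted p = 0.211 on day 2).

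Effects of ZnO and of ETEC at 6 h overlapped. Of the probes raised by ZnO, 262 were raised by ETEC, where independent lists would share 109, and 270 were lowered by it (172 for independent lists). Among those lowered by ZnO, 858 were lowered by ETEC (251) and 131 raised (160). In named genes these overlaps were 49, 23, 10 and 1. The correlation across probes of both effects was 0.289, and -0.00369 in simulations without any effect. The same pools entered both comparisons, and part of the excess may come from them.

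**Figure D2:**
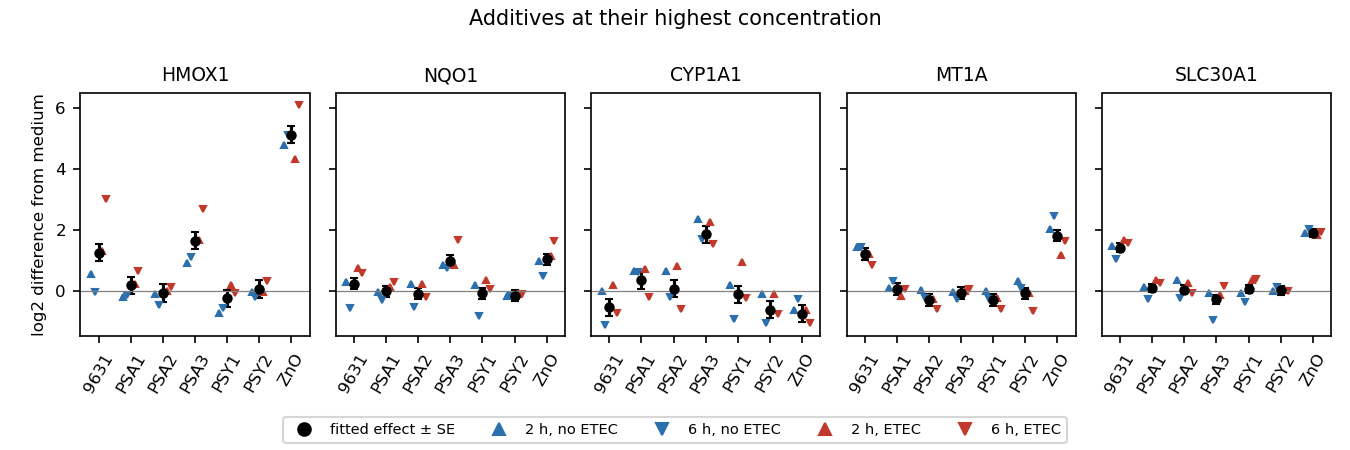
Log2 difference from medium of HMOX1, NQO1, CYP1A1, MT1A and SLC30A1 for each additive at its highest concentration. Black points with bars are the fitted effects ± SE and triangles the 4 conditions (2 h and 6 h, without and with ETEC); MT1A and SLC30A1 passed the threshold for 9631 and ZnO, CYP1A1 for PSA3, and HMOX1 and NQO1 for PSA3 and ZnO.

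ZnO at 0.0001% raised 2 named genes and lowered 15 against medium at 6 h, all near the threshold. SLC11A1, a metal transporter gene of phagocytes, rose by 1.51 ± 0.33 and the leptin gene LEP by 1.43 ± 0.28 (2 of 2 pools, adjusted p = 0.0499 each). PRPS2 fell by 2.55 ± 0.58, VDAC3 by 2.45 ± 0.53 and FKBP3 by 2.31 ± 0.52 (adjusted p = 0.0499 each), but these 3 rest on 1 array, and 4 of the 11 other FKBP3 probes had the opposite sign. On the arrays of the pool without ETEC they differed by 7.77, 7.31 and 7.05 on the log2 scale, and 413 probes were dimmer on that array by over 4, with 60.1% of them in 3 adjoining bands of 10 across the slide. Another 136 probes were brighter on it by over 4. Hypoxia and glycolysis and the respiratory chain were called lower and leukocyte markers higher with 0 of 13, 0 of 17 and 0 of 9 genes past the threshold (10 of the hypoxia genes lower adjusted over the list alone; adjusted p = 0.0229 each; 0.939 each with an estimated correlation).

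In limma's test 171 probes passed, 72 higher and 99 lower, of which 40 of the 99 and 0 of the 72 were far apart on that pool's arrays. Without the pool 2 passed, without ZnO 0.0001% with ETEC 472, and 0, 0, 0 and 1714 without the medium pools coded H and M without ETEC, the one coded M with ETEC and the one coded H with ETEC. SLC11A1 and LEP lost the threshold in 5 of these 6 fits and PRPS2, VDAC3 and FKBP3 in 4. There were 287 (90 higher, 197 lower) with normexp, 1 lower with quantile normalization, 0 with no filter and 0 with the value table, 1672 with slide and 2341 with scan day as a block, and 113 and 0 within days 1 and 2.

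Between the concentrations of ZnO, 198 named genes were higher at 0.01% and 25 lower. HSPA6 differed by 8.29 ± 0.56 (314-fold, adjusted p = 1.47e-08), HMOX1 by 5.49 ± 0.47 and RGS2 by 5.00 ± 0.49. GCSAM was at least 2.38-fold lower (adjusted p = 0.0352; -0.08 and 0.910 with normexp, 0.107 with quantile normalization), and IL6 was lower by -1.70 ± 0.40 and SLC11A1 by -1.58 ± 0.38. Heat shock proteins were higher in 8 of 14 cases (11 adjusted over the list alone), with DNAJB1 at 4.01, HSPA1L at 3.82 and HSPH1 at 3.68, and this call held with an estimated correlation (adjusted p = 1.03e-10; 0.0370 estimated). Immediate early genes were higher in 10 of 15 cases (12 adjusted over the list alone), with NR4A3 at 3.75, KLF4 at 2.83, KLF10 at 1.93 and KLF2, whose other probe had the opposite sign, at 2.06 (adjusted p = 4.15e-09; adjusted p = 0.0894 with an estimated correlation). Of 12 NRF2 genes 4 were higher, with TXNRD1 at 1.95, NQO1 at 1.38 and GCLM at 1.26 (adjusted p = 0.0287; adjusted p = 0.7098 with an estimated correlation). The test called 3199 probes, 1591 higher and 1608 lower. The split was 1383 and 815 with normexp, the count 1641 with the compared pools alone, 5919 and 5715 with slide and scan day as blocks, 571 and 2054 within days 1 and 2, 1287 without ZnO 0.01% without ETEC and 1762 without ZnO 0.0001% with ETEC. Without ZnO 0.01% with ETEC, IL6 (-0.81), TXNRD1 (adjusted p = 0.0726), NQO1 (0.0542) and GCLM (0.0782) did not pass, nor IL6 (-1.34, 0.115) and GCLM (0.118) without ZnO 0.0001% with ETEC. SLC11A1 and GCSAM did not pass without ZnO 0.0001% (0.0686 and 0.275) or ZnO 0.01% (0.0917 and 0.330) without ETEC. With the compared pools alone IL6 (0.123), GCLM (0.0866) and GCSAM (0.114) did not pass. Within days the list means were 2.33 and 2.30 for heat shock proteins, 1.88 and 1.59 for immediate early genes and 1.04 and 0.96 for NRF2, and with slide and scan day as blocks 2.26 and 2.28, 1.83 and 1.66, and 1.01 and 1.01.

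The preparation 9631 at 0.01% raised 4 named genes and lowered 0. SLC30A1 rose by 1.41 ± 0.14 (2.66-fold, adjusted p = 2.53e-07), MT1A by 1.21 ± 0.19 (2.32-fold, adjusted p = 0.00234), the glycosyltransferase gene B3GNT5 by 1.07 ± 0.15 (adjusted p = 0.000245) and KIAA1551 by 0.89 ± 0.17 (adjusted p = 0.0351), each in 4 of 4 conditions. SLC30A1 and MT1A are the genes of the zinc list that ZnO raised. Of this list 2 of 9 genes rose (2 adjusted over the list alone), with MT3 at -0.55 ± 0.27 and SLC30A9 at -0.52 ± 0.46 (adjusted p = 0.0108; adjusted p = 0.173 with an estimated correlation, and 0.254 within day 3). Its mean was 0.13 with the slide as a block, where its median was -0.03, 0.21 with the scan day, and 0.22 within day 3. MT3 was at 0.05 and 0.15 with these blocks. Immediate early genes and ribosomal proteins were called with 0 genes past the threshold (adjusted p = 0.00548 and 0.000224; 0.978 each with an estimated correlation).

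In limma's test 13 probes passed for 9631, 11 higher and 2 lower. They include single probes of ANXA1 (-1.78, adjusted p = 0.0359), CPT1A (0.85, 0.0351) and HMOX1 (1.39, 0.0421), genes whose brightest probe did not pass (HMOX1 1.25 ± 0.28, adjusted p = 0.0906; ANXA1 0.20, 0.701; CPT1A 0.83, 0.406). Splits were 14 and 7 with normexp, 19 and 7 with quantile normalization and 24 and 40 with the value table, and 99 probes passed with arrays as observations, 6 with slide as a block, 1 with the compared pools alone (SLC30A1 adjusted p = 0.0969, MT1A 0.502, B3GNT5 0.486, KIAA1551 0.766) and 759 (646 and 113) within day 3. SLC30A1 rose by 1.20 and 1.38 with slide and scan day as a block and 1.54 within day 3, MT1A by 1.29, 1.40 and 1.35, B3GNT5 by 0.89, 0.93 and 1.03 and KIAA1551 by 0.68 (adjusted p = 0.360), 0.93 and 1.25. The count was 20, 24, 89 and 7 without the 9631 pools at 2 h, at 6 h, with ETEC at 2 h and with ETEC at 6 h, and 6, 8, 6 and 8 without the medium pools at 2 h, 6 h (coded H), with ETEC at 6 h coded M and coded H. KIAA1551 lost the threshold in 7 of 10 such fits (adjusted p up to 0.167), while SLC30A1, MT1A and B3GNT5 did in 0.

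PSA3 at 0.052% raised 3 named genes and lowered 0. CYP1A1, a detoxifying enzyme induced through the aryl hydrocarbon receptor, rose by 1.85 ± 0.28 (3.60-fold, adjusted p = 0.00209), HMOX1 by 1.65 ± 0.28 (3.13-fold, adjusted p = 0.00839) and NQO1 by 0.99 ± 0.18 (1.99-fold, adjusted p = 0.0128), each in 4 of 4 conditions. Of the NRF2 list 2 of 12 genes rose (5 adjusted over the list alone), with GCLM at 0.58 ± 0.17 and TXNRD1 at 0.73 ± 0.23 (adjusted p = 7.23e-07; adjusted p = 0.154 with an estimated correlation). Ribosomal proteins were called lower with 0 of 17 past the threshold (adjusted p = 0.00117; adjusted p = 0.957 with an estimated correlation). The 7 probes that passed in limma's test are 3 of HMOX1, 2 of NQO1 and 2 of CYP1A1.

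With slide and scan day as a block and within days 1, 2 and 3, CYP1A1 rose by 1.82, 1.86, 1.33, 1.88 and 2.30, HMOX1 by 1.51, 1.65, 1.85, 1.96 and 1.29 and NQO1 by 0.95, 1.00, 1.02, 1.40 and 0.83. The list mean was 0.34, 0.31, 0.12 (median -0.12, adjusted p = 0.112), 0.44 and 0.42. Days 1 and 2 held the 6 h pools of PSA3 0.052% and day 3 those at 2 h, so these days also differ in time. The PSA3 count was 19 with arrays as observations, 20 with either block, 1558, 0 and 3 within the days, 3 with the letter M in the fit (HMOX1 and NQO1 adjusted p = 0.0582) and 0 with the compared pools alone (CYP1A1 0.112, HMOX1 0.146, NQO1 0.507), and 2 without PSA3 at 6 h and 2 without PSA3 with ETEC at 6 h. HMOX1 did not pass without PSA3 at 6 h (adjusted p = 0.0523), with ETEC at 2 h (0.0549) or with ETEC at 6 h (0.270), nor NQO1 without PSA3 at 6 h (0.164), with ETEC at 6 h (0.448), or medium with ETEC at 2 h (0.0679) or at 6 h coded M (0.0595).

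PSA1, PSA2, PSY1 and PSY2 at their highest concentrations changed 0 probes in limma's test, with 485, 1942, 1507 and 1237 at an unadjusted p under 0.05. For these 4 the 95% interval lay within 1 log2 unit of 0 for 81.9%, 79.7%, 78.8% and 78.1% of the named genes. With arrays as observations 93 probes passed for PSA2, with slide and scan day as blocks 317 and 164, and within day 3 24. For PSY1 the counts were 1 with scan day as a block, 1305 within day 3 and 2 without PSY1 with ETEC at 2 h, and for PSY2 10 within day 2. PSA1 gave 0 in each. For PSA1, camera called NF-kappaB regulators higher (0 of 8 past the threshold, mean 0.11, adjusted p = 0.0187) and ribosomal proteins lower (0 of 17, mean -0.25, adjusted p = 0.000596), both with adjusted p = 0.945 with an estimated correlation.

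At the lower concentrations PSA1, PSA2, PSA3 and PSY2 changed 0 probes against medium at 6 h in limma's test (2 pools against 4; 2168, 364, 4954 and 418 at an unadjusted p under 0.05). The 95% interval lay within 1 log2 unit of 0 for 66.0%, 69.1%, 59.3% and 66.2% of the named genes. Leukocyte markers were called higher for PSA3 with 0 of 9 past the threshold (4 adjusted over the list alone, mean 1.00, adjusted p = 0.00421; adjusted p = 0.336 with an estimated correlation). Counts were 1701 for PSA1 without its pool with ETEC, 1 without its pool without ETEC and 1 without the medium pool coded M without ETEC. They were 3 for PSA2 without its pool without ETEC, 682 for PSA3 with scan day as a block and 4498 within day 1, and 5 within day 2 for PSA2 and 5 for PSY2.

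Between highest and lower concentrations at 6 h the same 4 preparations differed in 0 probes (3128, 2423, 1897 and 1583 at an unadjusted p under 0.05), with intervals within 1 log2 unit for 52.2%, 48.8%, 54.4% and 51.8% of the named genes. NRF2 genes were called higher with PSA3 at 0.052% than at 0.0052% with 0 of 12 past the threshold (2 adjusted over the list alone, adjusted p = 1.28e-06; adjusted p = 0.283 with an estimated correlation). Interferon-stimulated genes were called for PSA2 (median -0.12, mean 0.15, adjusted p = 0.00119; adjusted p = 0.689 with an estimated correlation). Quantile normalization moved the median of all probes by 0.14, 0.13 and 0.14 for PSA1, PSA2 and PSA3. With slide as a block 43, 785, 82 and 28 probes passed and with scan day 223, 550, 271 and 39, while 0 passed within days. Without PSA1 0.0052% with ETEC 1697 passed for PSA1, and without PSA3 0.052% with ETEC 54 for PSA3.

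Ribosomal protein genes were also called with 0 of 17 past the threshold for lower concentrations of PSA1 (mean -0.39), PSA2 (0.37) and PSY2 (0.45), for highest against lower concentrations of PSA2 (-0.68) and PSY2 (-0.49) and for the change of the ETEC response by PSA1 (0.86) and PSA3 (0.49). With an estimated correlation, which was 0.811 for this list, their adjusted p was 0.990, 0.909, 0.941, 0.981, 0.869, 0.923 and 0.720. The median level of the list varied from 9.26 to 10.6 between slides and by up to 1.35 between arrays of a pool. Respiratory chain genes were called higher for PSY2 at 0.001% and lower for highest against lower concentrations of PSA2 and PSY2, interferon-stimulated genes lower for PSA2 at 0.001%, and hypoxia genes lower for PSY2 at 0.01% than at 0.001%, each with 0 genes past the threshold and an adjusted p of 0.869 to 0.981 with an estimated correlation.

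At their highest concentrations the preparations shared 2 values, 0.01% and 0.052%. Among 9631, PSA2, PSY1 and PSY2 at 0.01%, SLC30A1 (F = 39.1, adjusted p = 6.94e-07), MT1A (F = 23.4, adjusted p = 0.000225), B3GNT5 (F = 15.7, adjusted p = 0.00862) and KIAA1551 (F = 14.5, adjusted p = 0.0112) differed, each highest with 9631. Effects on MT1A were -0.29, -0.29 and -0.09 for PSA2, PSY1 and PSY2 against 1.21 for 9631, and those on SLC30A1 0.04, 0.06 and 0.01 against 1.41. In this F test 9 probes passed, 65 with arrays as observations, 17 with slide as a block, 14 with the letter M in the fit and 3 with the compared pools alone. Without the 9631 pools at 6 h, with ETEC at 2 h and with ETEC at 6 h the counts were 14, 4 and 3, and 41 without PSY1 with ETEC at 2 h. B3GNT5 did not pass without 9631 with ETEC at 2 h or at 6 h (adjusted p = 0.0519 and 0.212), nor KIAA1551 (0.132 and 0.105; 0.146 without 9631 at 2 h). Between PSA1 and PSA3 at 0.052%, CYP1A1 was at -1.51 ± 0.30 (adjusted p = 0.146), HMOX1 at -1.46 ± 0.31 (0.237) and NQO1 at -1.01 ± 0.19 (0.139), lower with PSA1 and short of the threshold. Limma called 0 probes (511 at an unadjusted p under 0.05, smallest adjusted p 0.0531), 9 with arrays as observations and 3 with normexp. For 76.8% of the named genes the interval lay within 1 log2 unit of 0. NRF2 genes were called lower with PSA1 (0 of 12 past the threshold, 2 adjusted over the list alone, adjusted p = 1.19e-05; adjusted p = 0.297 with an estimated correlation).

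**Figure D3:**
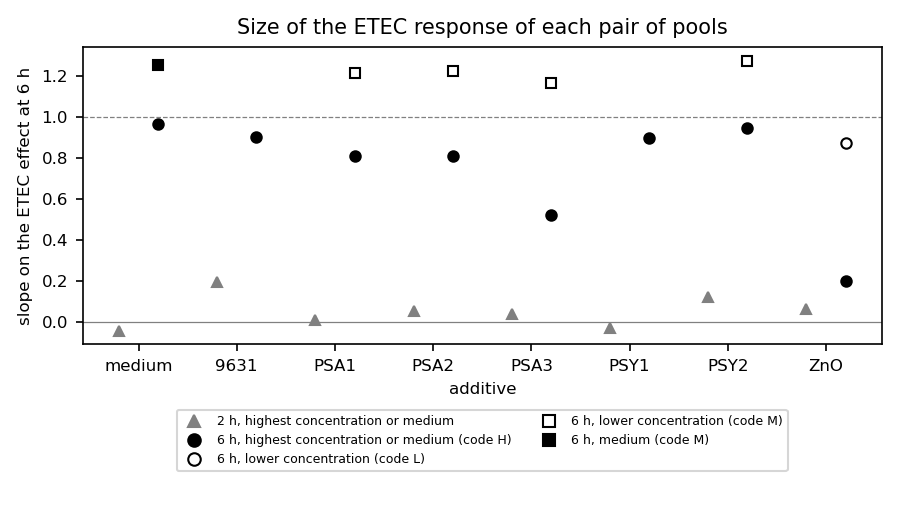
Size of the response to ETEC in each of the 22 pairs of pools, as the slope of the pair's log2 differences on the ETEC effect at 6 h (1 is the size of that effect). Triangles are pairs at 2 h, filled circles 6 h pairs at the highest concentration or medium coded H, the filled square medium coded M and open symbols lower concentrations; at 6 h slopes run from 0.203 for ZnO 0.01% to 1.28 for PSY2 0.001%, and at 2 h from -0.042 to 0.197.

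How additives changed the response to ETEC was tested as an interaction over both times, with both concentrations of an additive in 1 term. Limma called 0 probes for 9631, PSA1, PSA2, PSA3, PSY1, PSY2, ZnO and the F test of all (952, 2467, 648, 751, 428, 544, 2246 and 637 at an unadjusted p under 0.05). For ZnO this term joined pairs with slopes of 0.203 (0.01% at 6 h), 0.872 (0.0001% at 6 h) and 0.063 (0.01% at 2 h). The 0 calls therefore say little about 1 concentration at 6 h. These tests are wide, with intervals reaching a median of 0.973 to each side, or 1.09 for 9631 and PSY1, and intervals within 1 log2 unit for 24.8% (PSY1) to 46.1% (PSY2) of the named genes. For ZnO the inflammatory list was called lower with 0 of 15 genes past the threshold (mean -0.66, adjusted p = 0.00403; adjusted p = 0.874 with an estimated correlation). At 6 h alone each additive and concentration has 1 pool with and 1 without ETEC, so the spread comes from other groups. PSA1 0.0052% was scanned on day 3 without ETEC and on day 2 with it, so its change cannot be told apart from the scan day. Fits at this time, chosen after seeing the data, called 94 probes for 9631, 4 for PSA2, 55 for PSA3, 1 for PSY1 and 23 for ZnO at the highest concentrations, and 719 for PSA1, 3 for PSA2, 1 for PSA3 and 154 for ZnO at the lower ones. With arrays as observations 2 passed for 9631. Without the 9631 pool at 2 h 76 passed for 9631 and without the one with ETEC at 2 h 17. There were 4 for PSA3 without medium at 2 h, 3 for PSY1 without PSY1 at 2 h and 1 for ZnO without ZnO at 2 h.

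The effect of the additives differed between 6 h and 2 h for 136 named genes in an F test. Among those with the smallest p were CIDEB (F = 8.41, adjusted p = 0.0193), PRKAG1, a subunit of AMP-activated kinase (F = 8.14, adjusted p = 0.0196), DNAJC12 (F = 7.88, adjusted p = 0.0203) and PMEPA1 (F = 7.25, adjusted p = 0.0246). The test called 1405 of 27217 probes, 644 with normexp, 3378 with arrays as observations, 203 with slide and 2168 with scan day as a block. With the slide as a block CIDEB and PRKAG1 did not pass (adjusted p = 0.105 and 0.399). The count was 14 without 9631, 16 without PSY2, 2650 without PSA1 and 2391 without PSA3. Without 9631 CIDEB, PRKAG1, DNAJC12 and PMEPA1 did not pass (adjusted p = 0.207, 0.223, 0.124 and 0.0564), nor the first 3 without PSY2 (0.0579, 0.0858 and 0.0554) or PMEPA1 without ZnO (0.0621).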

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

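Of the tests in this part, those of a mislabelled sample, of prior movement by ZnO as the whole cause, of the lower concentration as the whole cause of the letter's pattern and of a lower response with ZnO and both tests of the probes seen only with ETEC were chosen after the result was seen, as were the split by pool letter and the fits at 6 h alone. The other tests were fixed before their own result was seen, but the fits by scan day among them were added after seeing the data.

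In 7 of 51 sets of 4 to 8 values, 1 value lay far from the others by Dixon's ratio, where chance gives about 1 in 20 sets. With PSA3, NQO1 differed from medium by 1.67 at 6 h with ETEC, against 0.75 to 0.83 in the other 3 conditions. With ZnO 0.01% at 6 h with ETEC, RGS2 stood at 3.25 (others 4.27 to 4.46), DNAJB1 at 3.83 (2.67 to 2.84), TXNRD1 at 2.90 (0.97 to 1.09) and BTG2 at 0.71 (2.57 to 2.91). With ZnO at 6 h without ETEC, AURKB stood at -1.13 (others -0.21 to -0.10), and at 2 h with ETEC CCK stood at 1.07 (-0.19 to -0.04). Of these 7 values 4 are for ZnO with ETEC at 6 h, and as differences from medium they can come from either side: TXNRD1 was at 6.79 and 6.98 without and with ETEC in the ZnO pools and at 5.70 and 4.09 in medium.

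Tests of a difference between groups called 2012 probes for the effect of ETEC at 6 h against 2 h and 1405 for the effect of the additives at 6 h against 2 h, both described in the report. For the effect of ETEC at 6 h, 1841 probes differed between pools with the letter M in their code and the others, and 23 between the pair with ZnO 0.01% and the other pairs.

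The response to ETEC at 6 h was smaller in the only pair of pools with ZnO 0.01%, so the spread in its tests comes from other groups, and the test over both times called 0 probes for ZnO. The slope of that pair on the effect of ETEC was 0.203, with 68.1% of 1425 probes in the same direction, against 0.525 to 1.28 in the other 13 pairs. DDIT4 rose by 0.65 with ETEC in this pair against 5.13 (SD 0.48) in the others (interaction -4.48, adjusted p = 0.000503), and GDF15 by 0.28 against 3.19 (adjusted p = 0.000219). TNFAIP3 (interaction -2.70, adjusted p = 0.0288), STC2 (-3.57, 0.0409) and CXCL2 (-2.49, 0.0479) also rose less, while KITLG fell by 2.05 in this pair and 2.03 in the others.

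Against a pool labelled with ETEC that had received none, the 2 probes that rise with ETEC at 2 h were above background on 28 of 28 arrays with ETEC at 6 h, those of this pool included, and their fitted rise in this pair was 6.22, no exact value since they were near background without ETEC. Scan day is excluded as the cause, since the slope of the pair was at most 0.243 within a day. On the 290 probes that ZnO alone moved by under 0.5 the slope was 0.457, below the other pairs (0.740 to 1.21) and 3.71 SD under their mean. This argues against prior movement of the same transcripts by ZnO as the whole cause. It does not exclude it, since the rule was chosen after the result and rests on 1 pair. These probes may also have been moved by up to 0.5. CXCL2 was at 1.91 with ZnO alone and 1.65 with ETEC added, against 2.26 and 4.33 in medium. As a part of the cause prior movement by ZnO stays open, since 0.457 is under the bound of 0.5 by less than the spread (SD 0.147). DDIT4 was at 6.22 with ZnO alone and 6.86 with ETEC, against 3.13 and 8.32 in medium. The interaction sets this pair against the others, so with its small slope most called probes are bound to oppose the effect of ETEC. It restates that slope and is no separate support for a lowered response. Of the 23 probes called in the interaction 22 opposed the effect of ETEC (65 of 68 with the letter M in the fit, 119 of 122 with arrays as observations, 207 of 212 and 211 of 217 with scan day and slide as blocks), so a lowering of the response by ZnO is a hypothesis, resting on 1 pair of pools.

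The effect of ETEC at 6 h differed in pools whose code holds the letter M, more often towards a larger effect: of 1841 called probes, 294 raised by ETEC in the other pools were higher in M and 904 lowered by it were lower. There, 7594 probes passed in 5 pairs and 3627 in the other 9 pairs. The other pairs include those with the smallest slopes, ZnO 0.01% (0.203) and PSA3 0.052% (0.525), so part of the difference may come from them. Both are also among the additive pairs compared below. IVL rose by 5.10 against 1.82 (adjusted p of the difference 7.67e-05), CCL20 by 5.10 against 2.10 (0.000288), CSF2 by 4.66 against 2.43 and NFKBIA by 3.21 against 1.40. ISG15 rose by 1.67 in these pools and was at -0.07 in the others (0.000236). DDIT3 rose less, by 0.98 against 2.37 (0.0227), as did BMP4 (0.29 against 1.43, 0.0115). Without ETEC 1 probe differed by the letter.

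In pools with an additive the letter follows the concentration level in the sample titles, and of these 5 pairs 4 hold a lower concentration. The other holds medium alone, where no label says what the letter means. Of 2293 probes called from the additive pairs alone, 72.9% (0.729 of them) differed in the same direction between the medium pairs, which lies between the bounds of 0.6 and 0.8 set for this test. The slope of the medium pairs' difference on that of the additive pairs was 0.318, where differences between additive pairs coded H reached 0.404, so the lower concentration and the letter cannot be told apart with 1 medium pair per letter. Other values go against the concentration as the whole cause. The medium pair coded M had a slope of 1.26 on the effect of ETEC (1.17 to 1.28 in the additive pairs coded M, 0.969 in medium coded H), and ZnO 0.0001%, not coded M, had 0.872. IVL rose by 5.02 and 1.52 in the medium pairs coded M and H. But it was picked for its difference by letter, which includes these pairs, so it is no separate evidence. With arrays as observations 2889 probes were called, of which a share of 0.595 was also called with scan day as a block and 0.551 with the slide, so neither is the whole cause. An effect of the concentration is the only biological explanation that was tested.

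At 6 h, 4 probes near background without ETEC rose with it, by at least 65.4-fold, 29.5-fold, 17.9-fold and 4.76-fold, and 0 of them has a gene name. At 2 h 2 of them were called, and the other 2 were not (adjusted p = 1.00 each). With ZnO 0.01% their mean fitted rise had a ratio of 0.983 to that of the other pairs, but 1 of the 4 did not follow (0.04), and rises from near background are no exact values, so this ratio decides nothing. They may be pig transcripts or RNA of the added bacteria, and fewer than 5 probes cannot tell these apart. Probe sequences were not analysed here.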

How the results depend on the processing

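In this part the fits with scan day as a block or within a scan day, with the letter of the pool code, without the least agreeing pool, without probes far apart on the arrays of a pool, and at 6 h alone were chosen after the result was seen. The other settings were chosen before, and the cause of a change was not tested.

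Counts of probes past the threshold moved by over 1.5 times, or began or ended, in 111 cases over the settings, and stayed within that in 283. With normexp there were 0 for ETEC at 2 h, 4309 for ETEC at 6 h, 1268 for the difference of the times, 1291 for 6 h against 2 h, 21 for 9631, 1602 for ZnO, 644 for additive by time, 287 for ZnO lower, 1 for PSA3 highest against lower and 3 for PSA1 against PSA3. With quantile normalization 26 passed for 9631 and 1 for ZnO lower. With no filter 0 passed for ZnO lower and 1 for PSA1 highest against lower, and with the value table of the authors 64 for 9631, 1 for ETEC at 2 h, 1 for PSA1 lower and 0 for ZnO lower. A probe was tested when well above background on both arrays of at least 2 pools, and may lie near background in the others. Whether such probes account for the changed counts was not tested.

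With arrays as observations there were 4 for ETEC at 2 h, 99 for 9631, 93 for PSA2, 19 for PSA3, 3378 for additive by time, 6 for PSA3 lower, 1385 for ZnO lower, 20, 90, 21 and 13 for PSA1, PSA2, PSA3 and PSY2 highest against lower, 2 for the change of the ETEC effect by 9631, 9 for PSA1 against PSA3 and 65 for the F test at 0.01%. With the hybridisation number as a replicate block these were 4, 97, 92, 19, 3346, 13, 1228, 5, 68, 18, 9, 2, 9 and 63. Hybridisation numbers do not pair the pools: the difference between first and second array had a median correlation between pools of 0.0251 (-0.699 to 0.834, 946 pairs of pools).

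With the slide as a block 5 passed for ETEC at 2 h, 3294 for the difference of the times, 18 for 6 h against 2 h, 6 for 9631, 317 for PSA2, 20 for PSA3, 203 for additive by time, 1672 for ZnO lower, 43, 785, 82, 28 and 5919 for PSA1, PSA2, PSA3, PSY2 and ZnO highest against lower, 2 for the ETEC effect by 9631, 9 for PSA1 against PSA3 and 17 for the F test. With scan day these were 4, 3102 and 1804, then 164 for PSA2, 20 for PSA3, 1 for PSY1, 2168 for additive by time, 3, 682 and 2341 for PSA1, PSA3 and ZnO lower, 223, 550, 271, 39 and 5715 for highest against lower, 2 for the ETEC effect by 9631, 10 for PSA1 against PSA3 and 65 for the F test. With the letter M in the fit 3648 passed for ETEC at 6 h, 1146 for the difference of the times, 3 for PSA3, 0 for ZnO lower, 3 for PSA1 against PSA3 and 14 for the F test. Without the least agreeing pool 0 passed for ZnO lower and 1 for PSA1 against PSA3, and without probes far apart on the arrays of a pool 1 for PSA1 highest against lower and 1 for PSA1 against PSA3.

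With only the compared pools 1 passed for ETEC at 2 h, 1798 for 6 h against 2 h, 1 for 9631, 0 for PSA3, 1816 for ZnO, 0 for ZnO lower, 205, 108, 204 and 1641 for PSA2, PSA3, PSY2 and ZnO highest against lower and 3 for the F test, and in medium alone 806 for ETEC at 6 h. For the change of the ETEC effect at 6 h alone there were 94 for 9631, 4 for PSA2, 55 for PSA3, 1 for PSY1 and 23 for ZnO, and at the lower concentrations 719 for PSA1, 3 for PSA2, 1 for PSA3 and 154 for ZnO.

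Leaving out 1 pool, or all pools of an additive, gave 1 to 2 probes for ETEC at 2 h, 5492 to 7660 at 6 h, 1483 to 2128 for their difference, 1472 (without PSA1) to 4354 for 6 h against 2 h, 6 (without medium at 2 h) to 89 (without 9631 with ETEC at 2 h) for 9631, 2 (without PSA3 at 6 h) to 9 for PSA3, 0 to 2 for PSY1 and 1963 to 3088 for ZnO. The range was 14 (without 9631) to 2650 (without PSA1) for additive by time, 3 (without 9631 with ETEC at 6 h) to 41 (without PSY1 with ETEC at 2 h) for the F test and 0 to 1 for PSA1 against PSA3. It was 0 to 76, 4, 3 and 1 for the ETEC effect by 9631, PSA3, PSY1 and ZnO. For lower concentrations it was 0 to 1701 (without PSA1 with ETEC) for PSA1, 0 to 3 for PSA2, 0 to 1 for PSA3 and PSY2 and 0 to 1714 (without medium coded H with ETEC) for ZnO, and for highest against lower 0 to 1697, 5, 54 and 1 for PSA1, PSA2, PSA3 and PSY2 and 1287 to 2475 for ZnO. For PSA1, PSA2 and PSY2 at the highest concentration it was 0 to 0.

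Of 153 pairs of a named gene and a comparison, 30 lost the threshold at least once when a pool was left out and 0 changed sign. Over the other settings, fits within a scan day apart, 158 of 1856 values lost it and 13 changed sign. With the slide as a block 6 h against 2 h reversed for PTMA (-0.005), PRRT1 (-0.22), RPL6 (-0.28), P2RY6 (-0.37), PNLIP (0.053), AMBP (0.072) and OBP2B (0.73), and with scan day for PTMA (-0.23), RPL6 (-0.31) and P2RY6 (-0.023). MT3 with 9631 reversed in these blocks (0.053 and 0.15), and FAS with ETEC at 6 h in medium alone (-0.10). Within day 3 SRSF6 (0.36), GCLM (0.04) and NQO1 (0.01) reversed for ETEC at 6 h and RAB3A (-0.15), PTMA (-0.12), RPL6 (-0.06), HNF4A (-0.35) and ANG (-0.10) for 6 h against 2 h. For ZnO, CCNB1 reversed within day 3 (0.03), CCK within days 1 (-0.002) and 2 (-0.14) and SLC30A7 within day 2 (-0.07), where SPDEF was at 0. Of 61 calls of gene lists 12 were left with an estimated correlation: inflammatory, NF-kappaB, integrated stress and EGFR lists for ETEC at 6 h and for the difference of the times, immediate early genes for that difference, heat shock and immediate early genes for ZnO and heat shock for ZnO highest against lower. By fry 0 lists passed for ETEC at 2 h (3 by camera), 13 for ETEC at 6 h (9), 10 for the difference of the times (10), 0 for 6 h against 2 h (2), 1 for 9631 (3), 0 for PSA3 (2), 6 for ZnO (7), 12 for ZnO lower (3), 1 for PSA3 lower (1) and 9 for ZnO highest against lower (3), and 0 for the other comparisons.

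Other splits of the pools were counted for comparisons of at least 3 pools. The real grouping counts as 1 of the splits, and the bound was a share under 0.05. Chance is excluded for ETEC at 6 h (1 of 100 splits gave as many probes as the real 6783, highest other 3685). The difference of the times met the bound (1 of 100, real 2012, highest other 0). Those splits also mixed pairs of different additives, which adds additive effects to the residual, so they do not exclude chance. For 6 h against 2 h (1 of 100, real 3293, highest other 1886) chance is excluded, but time and scan day overlap there. The splits cannot tell time and scan day apart. ZnO (1 of 36, real 2776, highest other 2164) and PSA3 (1 of 36, real 7, highest other 1) met the bound. But 1 of 36 is the lowest share possible and was not adjusted over the additives, so these splits alone do not exclude chance. The F test at 0.01% met the bound (2 of 100, real 9), but another split gave 1156 probes, so chance is not excluded there. Nor is it for ETEC at 2 h (5 of 100, real 2, highest other 147) or 9631 (5 of 36, real 13, highest other 4633). For PSA1, PSA2, PSY1 and PSY2 the real count was 0, with 36 of 36 splits each (highest other 0, 0, 2 and 2). The splits with 4633 and 1156 probes point to a structure of the samples. The first exchanges the 2 h pools of 9631 and medium, which leaves the 6 h pools of 9631, all scanned on day 3, against medium of days 1 and 2, and within day 3 759 probes passed. Splits were too few for a share under 0.05 for the change of the ETEC effect by PSA1, PSA2, PSA3, PSY2 and ZnO (12 of 12 each; real 0, highest other 0) and for PSA1 against PSA3 (8 of 8; real 0, highest other 0).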

Other observations

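The genes of this part, and the comparisons between them, were chosen after their values were seen, and the hypotheses rest on the same data. ETEC at 6 h raised transcripts of some innate defence genes and lowered others, which were not tested as a group. Neither the interferon list nor that of mucins and epithelial defence was called for ETEC at 6 h. The cytokine gene IL6 rose by 1.45 ± 0.15, the chemokine gene CCL5 by 2.07 ± 0.34 and the acute phase gene SAA3 by 1.59 ± 0.27. Within the interferon list GBP1 rose by 1.46 ± 0.15, IRF1 by 1.08 ± 0.18, MX2 by 0.72 ± 0.26 and IFIH1 by 0.57 ± 0.10, while IRF7 fell by 0.44 ± 0.11, IRF9 by 0.40 ± 0.12 and STAT2 by 0.33 ± 0.12. The defensin gene DEFB1 fell by 0.66 ± 0.11, DMBT1 by 0.77 ± 0.12 and the endotoxin receptor gene TLR4 by 0.67 ± 0.17. Of 14 chaperone genes 4 fell and 0 rose, without a call of the list (adjusted p = 0.108), among them HSPA8 by 0.72 ± 0.24, HSP70.2 by 0.53 ± 0.18 and DNAJB1 by 0.40 ± 0.11. SOX9 rose by 2.57 ± 0.20 and MT1A by 0.92 ± 0.11.

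Several genes raised by ETEC at 6 h were also raised by ZnO at 0.01%. They were picked from several lists, and the integrated stress list was not called for ZnO (adjusted p = 0.177). With ZnO, DDIT3 rose by 2.41 ± 0.30, HBEGF by 1.88 ± 0.34, PMAIP1 by 1.59 ± 0.37, DDIT4 by 1.53 ± 0.43, GADD45A by 1.53 ± 0.39, TNFAIP3 by 1.20 ± 0.30 and VEGFA by 1.05 ± 0.20. These are averages over the conditions. At 6 h with ETEC, DDIT4 stood at 6.86 with ZnO against 8.32 in medium, TNFAIP3 at 1.95 against 2.70 and GADD45A at 4.55 against 4.60. The other genes of this group were higher with ZnO there. ETEC and ZnO had opposite directions for IL6, HSPA6, DNAJB1, TXNRD1 and NQO1. The smooth muscle gene CNN1 rose by 2.26 ± 0.37 with ZnO, the polarity gene PARD6B by 0.94 ± 0.16 and the claudin gene CLDN4 by 0.77 ± 0.24.

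The preparation 9631 and ZnO 0.01% both raised MT1A and SLC30A1. With 9631 the chaperone genes HSPA6 (0.70 ± 0.36) and DNAJB1 (-0.21 ± 0.18) did not pass, and with ZnO 0.0001% neither did MT1A (-0.09 ± 0.29) nor SLC30A1 (-0.05 ± 0.21). A candidate explanation is that 9631 carries zinc or another metal that these genes respond to, at a dose below that of ZnO 0.01%. The comparison called 6 probes with the slide as a block and 99 with arrays as observations. Metal content of the preparation by mass spectrometry, and the same incubation with a zinc chelator, would test it.

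With 9631 and ETEC at 6 h, TXNRD1 stood at 5.77, against 5.80 with 9631 alone, 5.62 and 5.78 in medium and 4.06 and 4.12 in medium with ETEC, and HMOX1 differed from medium with ETEC by 3.00 (-0.04 without ETEC at 6 h). The interaction over both times was short of the threshold for both (TXNRD1 0.87 ± 0.45, HMOX1 1.99 ± 0.46, adjusted p = 0.940 each), and the test at 6 h alone, with 1 pool per arm and the spread of other groups, called 94 probes. Both 6 h pools of 9631 were scanned on day 3, so a shift common to that day would cancel in the effect of ETEC within 9631. With PSY1, also scanned on day 3 at 6 h, HMOX1 differed from medium by -0.55 without and -0.08 with ETEC. A deviation of single pools was not tested. An NRF2 response that 9631 keeps up in the presence of ETEC is a hypothesis resting on 1 pool per arm. Replicate cultures at 6 h scanned together, with NRF2 knocked down, would test it.

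PSA3 raised CYP1A1, HMOX1 and NQO1, and at 0.0052% they stood at 0.48 ± 0.40, -0.14 ± 0.41 and -0.33 ± 0.24. Compounds in PSA3 that bind the aryl hydrocarbon receptor are a candidate explanation, with 19 probes called with arrays as observations, 20 with the slide as a block and 0 with the compared pools alone. A receptor antagonist added with PSA3, and a dose series of purified polysaccharide, would test whether the polysaccharide itself is needed.

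The smaller effect of ETEC with ZnO 0.01% may come from fewer or less active bacteria, from cells that no longer respond, and in part from transcripts already moved by ZnO. Values argue against prior movement by ZnO as the whole cause (slope 0.457 on probes that ZnO alone moved by under 0.5, against 0.740 to 1.21 in the other pairs). With 1 pair they do not exclude it. Counts of adherent bacteria and a dose series between 0.0001% and 0.01% would tell these explanations apart. For the 4 probes seen only with ETEC, an alignment of the probe sequences to the pig and E. coli genomes, or RNA of the bacteria alone on the array, would show which organism they may measure.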
